A study of Homo sapiens with 12 samples.

How the data were processed

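Total RNA was isolated with NucleoZOL and made into Illumina sequencing libraries by a standard procedure, per the labels' protocols. The 12 libraries are 3 replicates each of PC9 control cells and AGR2-knockdown cells at 24 h of 300 nM gefitinib, and of control cells and AGR2-overexpressing cells at 72 h. Per the submitters' processing notes, reads were aligned with STAR 2.7.8a to the human genome hg38/GRCh38. The quantifier, the annotation release and the strandedness of the libraries are not given in the sources used here. The authors deposited 1 table of TPM (transcript abundances scaled to a fixed total per library) with 30225 genes, of which 21485 had a symbol. Each library summed to 1000000 TPM over the listed genes, and 4771 values lay between 0 and 1e-06. TPM keep no read counts, so the depth of each library is unknown and no count-based interval or test is given. By biotype the table held 16053 protein-coding, 10322 long non-coding and 3381 pseudogene entries. Transcript length and GC content came from GENCODE release 29, to which 25380 gene IDs (84.0%) matched. Coordinates of genes are those of the deposited table, with the end taken as 1 less than its stop.

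The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with at least 1 TPM in at least 3 of the 12 libraries were tested, 15721 in all. Values were taken as log2(TPM + 1) and fitted in limma 3.58.1 under R 4.3.3 with the 4 group means as a model over all 12 libraries, which leaves 8 residual degrees of freedom. Contrasts were knockdown minus control at 24 h, overexpression minus control at 72 h, 72 h minus 24 h control, and the overexpression effect minus the knockdown effect. Moderated tests with an intensity trend (eBayes) were two-sided, and p was adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. A permutation test of 3 against 3 libraries cannot go below 0.1. Of 30 gene lists, 29 had at least 3 tested members, the exception being neuroendocrine markers, which gives no value. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Overlap of the knockdown and overexpression calls was tested with Fisher's exact test. Group means are given with the SD over 3 libraries, and fold changes of single genes as log2 with the SE of the limma fit.

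Named genes were AGR2, the 12 largest rises and 12 largest falls for the knockdown and the overexpression, and the 8 largest of each for the controls. These had to pass the test, have a symbol, reach a mean of at least 5 TPM in the higher group and show no overlap between the libraries of the groups. The 8 genes with the largest smaller change in each of the opposite and same-direction classes, and up to 4 members with the largest change in each described list, were added. The list members named with a change in the knockdown or the overexpression likewise showed no overlap between the 3 libraries of each group. EGR1, although among the largest changes of its list only with overexpression, is also named in the knockdown, since it was 1 of 2 members that fell. In the control comparison list members are named only where the rule by size names them. Some genes that these rules select are not reported here.

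Alternatives were other pseudocounts, other filters on low values, rescaling of each library by the median ratio to the geometric mean, quantile normalisation, the 6 compared libraries alone, a block for the replicate number, robust shrinkage, library weights, a 2-fold minimum and leaving out each library in turn. After the data were seen, further alternatives were added, namely protein-coding nuclear genes alone, removal of each library's trend on transcript length and GC content, leaving out the libraries lowest in long transcripts (control replicate 1 at 24 h and overexpression replicate 1), and leaving out genes that overlap a gene on the other strand, of which 8407 were tested. An estimated correlation was then also used for lists with rescaled libraries and in these settings, the last excepted. The procedure was tested on simulated data, where a log2 change of 1 was found in 95.5% of altered genes and a change of 0.5 in 62.7% for the knockdown libraries, with 3.41% of calls false. For the overexpression libraries these were 94.0%, 65.7% and 6.52%. The simulation altered few genes, all with a control mean of about 5 TPM or more, in nearly equal numbers up and down. Its noise was independent between genes, with no shift of the median gene and no trend on transcript length or GC content. Its shares of found and false calls therefore need not hold for these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.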

Results

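RNA sequencing was carried out on PC9 cells, a non-small cell lung cancer line with an activating EGFR mutation. All 12 libraries came from cells given 300 nM gefitinib, an inhibitor of the EGFR kinase. The 4 groups of 3 libraries were controls and AGR2-knockdown cells after 24 h of the drug, and controls and AGR2-overexpressing cells after 72 h. The comparisons ask which genes AGR2 regulates in these cells under gefitinib. AGR2 is a protein disulfide isomerase family member of the endoplasmic reticulum, known for its part in mucin production. Cells without gefitinib were not analysed here, so the effect of the drug itself is not measured. The labels number 3 replicates per group and do not say whether they were separate cultures. Each limma p therefore sets a change against the spread between these libraries, pooled over the 4 groups, which need not be that between cultures. Values were TPM, a transcript abundance scaled to a total of 1000000 per library. TPM keep no record of read numbers, so the depth of each library is unknown. Between 12130 and 14589 genes per library reached 1 TPM.

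AGR2 RNA (ENSG00000106541, chromosome 7, 16791811 to 16833433, minus strand, GRCh38) was 47.5-fold lower in the knockdown than in its control at 24 h. It stood at 31.95 ± 0.868 TPM (SD, n = 3) in the controls and 0.673 ± 0.0893 TPM in the knockdown, and each of the 3 knockdown libraries was below each control. By limma the log2 fold change was -4.30 (SE 0.065, adjusted p = 1.26e-10). At 72 h AGR2 was 1.38-fold higher in the overexpressing cells, at 11.2 ± 0.808 against 8.11 ± 0.481 TPM (log2 fold change 0.42, adjusted p = 0.000325), with 3 of 3 libraries above every control. The 72 h controls held 3.94-fold less AGR2 RNA than the 24 h controls, so the overexpressing cells had 0.35 times the level of the 24 h controls. The annotated span of AGR2 overlaps a gene on the other strand, and whether reads were counted by strand is not given in the sources used here.

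**Figure D1:**
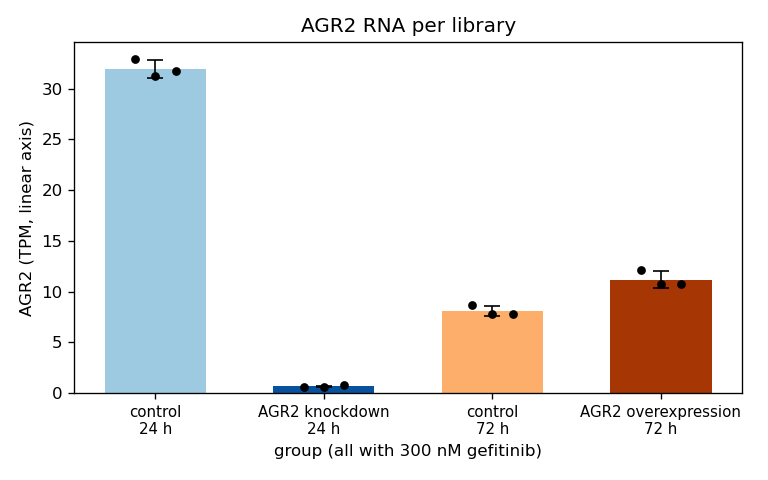
AGR2 RNA in TPM on a linear axis that starts at 0, for the 4 groups. Bars are group means, whiskers are 1 SD (n = 3), and dots are single libraries. The 24 h controls lie between 31.2 and 32.9 TPM and the knockdown libraries below 1 TPM. The overexpressing libraries start at 10.7 TPM, above the highest 72 h control at 8.67 TPM.

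The libraries separated by group. Within groups, correlations of log2 values ran from 0.9718 to 0.9915, and between groups from 0.8771 to 0.9629. The first principal component, with 45.3% of the variance, set the knockdown (56.6 to 59.4) and the overexpressing cells (-58.8 to -56.7) on opposite sides of both control groups (-1.46 to 3.92). The third, with 15.5%, set the knockdown (15.84 to 20.05) and the overexpressing cells (14.18 to 25.98) above both control groups (-40.73 to 6.29). Transcripts of the mitochondrial genome held 45.0% ± 2.11 of TPM in the 24 h controls (SD, n = 3) and 36.6% ± 0.479 in the knockdown. They held 42.1% ± 0.902 in the 72 h controls and 43.5% ± 5.39 in the overexpressing cells. Pseudogenes held 25.9% ± 0.971 of TPM in the 24 h controls and 29.1% ± 0.269 in the knockdown. Their share was 24.2% ± 0.382 in the 72 h controls and 20.9% ± 2.81 in the overexpressing cells. Nuclear protein-coding genes held between 23.9% and 33.8% per library. The median tested gene was higher by 0.35 on the log2 scale in the knockdown than in its control. The same shift was 0.30 between the control groups and 0.025 for the overexpression. The knockdown and the control comparison share the 24 h controls, so their shifts and rises are not independent. The median TPM of tested protein-coding genes averaged 3.75 in the 24 h controls. It averaged 5.53 in the knockdown, 5.51 in the 72 h controls and 5.58 in the overexpressing cells. Shifts of gene lists are therefore given relative to the median of all tested genes, while fold changes of single genes are as deposited. For single genes, means are given with the SD (n = 3) and the log2 fold change follows in parentheses; genes said to rise or fall passed limma at an adjusted p below 0.05. The shift between libraries also followed transcript length and GC content. From the shortest to the longest eighth of transcripts the median change went from 0.18 to 0.53 in the knockdown, 0.1 to -0.08 in the overexpression and -0.08 to 0.57 between the controls. From the lowest to the highest eighth of GC content it went from 0.51 to 0.13, 0.07 to 0.12 and 0.29 to 0.38.

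**Figure D2:**
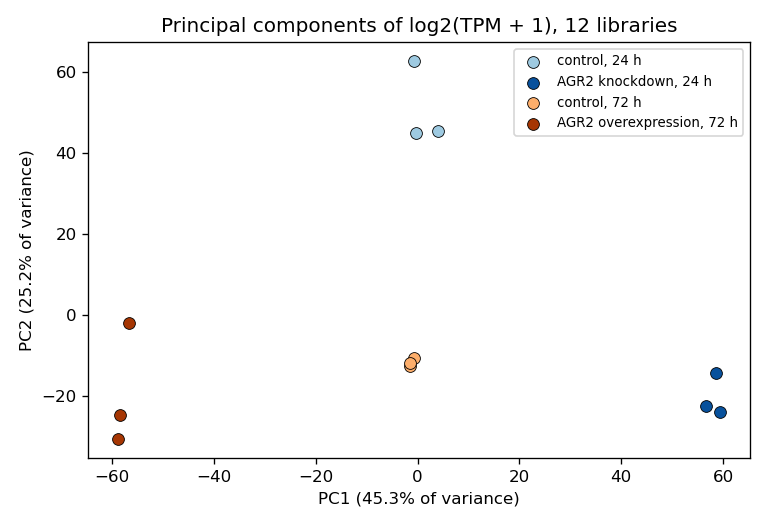
Scores of the 12 libraries on the first principal component (horizontal axis, 45.3% of the variance) and the second (vertical axis, 25.2%) of log2(TPM + 1), coloured by group. Knockdown libraries lie at 56.6 or more on the horizontal axis and overexpressing libraries at -56.7 or less, with both control groups between them. The 24 h controls lie at 44.9 or more on the vertical axis.

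The comparison of AGR2-knockdown cells with their controls at 24 h asks which genes change when AGR2 is lowered. S100A9, a calcium-binding protein of inflammation, rose from 1.04 ± 0.341 to 67.8 ± 2.80 TPM (log2 fold change 5.09, SE 0.16, adjusted p = 5.15e-09) by limma with n = 3 per group. The cancer-testis antigen MAGEC2 rose from 2.15 ± 0.0150 to 78.6 ± 2.25 TPM (log2 fold change 4.66, SE 0.071, adjusted p = 1.26e-10). VIM, the mesenchymal intermediate filament vimentin, rose from 4.29 ± 0.183 to 54.3 ± 2.28 TPM (3.38), and FOSL1, a subunit of the AP-1 transcription factor, from 8.70 ± 0.799 to 110.5 ± 5.39 TPM (3.52). G0S2, an inhibitor of triglyceride breakdown, rose from 11.2 ± 1.41 to 134 ± 13.4 TPM (3.47). The protein cross-linking enzyme TGM2 (3.70), NAP1L2 (3.40), the secreted hormone STC2 (3.32), the secreted ribonuclease RNASE1 (3.25), CDCA7 (3.18), the metallothionein MT1E (3.17) and the chromatin protein HMGA2 (3.0) made up the rest of the 12 largest rises.

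The largest fall in the knockdown was that of CYBA (chromosome 16, 88643275 to 88651083), which encodes a membrane subunit of NADPH oxidase, from 34.3 ± 6.68 to 0.379 ± 0.0471 TPM (log2 fold change -4.66, SE 0.11, adjusted p = 9.92e-10). KRT13, a keratin of stratified epithelia, fell from 55.35 ± 6.00 to 1.455 ± 0.197 TPM (log2 fold change -4.52, SE 0.12, adjusted p = 1.57e-09). The surface proteins PSCA, from 61.7 ± 10.0 to 3.38 ± 0.133 TPM (-3.83), and CEACAM6, from 49.3 ± 4.48 to 3.14 ± 0.299 TPM (-3.60), fell as well. The calcium-binding protein S100P fell from 56.0 ± 8.20 to 3.38 ± 0.414 TPM (-3.70), and the aldehyde dehydrogenase ALDH3A1 from 249.6 ± 27.4 to 14.7 ± 1.46 TPM (-4.0). The alkaline phosphatases ALPG (-4.22) and ALPP (-3.95) and the uroplakin-like UPK3BL2 (-3.13) fell, and each has a near-identical paralog with which reads could be shared. The troponin TNNC1 (-3.22) and the antisense RNA RCC2-AS1 (-3.77) also fell, the latter from control libraries as far apart as 42.4, 12.6 and 3.31 TPM.

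Cell-cycle genes rose together in the knockdown. Of 28 tested genes of DNA replication and S phase 28 rose (median 1.55 relative to all genes, camera adjusted p = 8.28e-12, adjusted p = 0.0621 with an estimated correlation). Examples are the replicative helicase subunits MCM2 from 4.56 ± 0.580 to 34.9 ± 2.87 TPM (2.69) and MCM3 from 7.95 ± 0.411 to 47.0 ± 2.18 TPM (2.42), the replication licensing factor CDC6 from 1.77 ± 0.142 to 16.8 ± 0.952 TPM (2.68) and the flap endonuclease FEN1 from 22.8 ± 0.640 to 136 ± 2.11 TPM (2.52). Of 26 genes of mitosis and G2/M 26 rose (median 1.01 relative to all genes, camera adjusted p = 7.1e-08, adjusted p = 0.158 with an estimated correlation). TOP2A rose from 11.3 ± 1.92 to 52.2 ± 5.15 TPM (2.12), the transcription factor FOXM1 from 18.3 ± 1.84 to 70.95 ± 2.47 TPM (1.91) and the kinase CDK1 from 15.7 ± 1.60 to 57.45 ± 2.79 TPM (1.81). Of 20 genes that ERK signalling induces 18 rose and 2 fell (median 0.96 relative to all genes, camera adjusted p = 0.000799, adjusted p = 0.484 with an estimated correlation). DUSP6, a phosphatase that inactivates ERK, rose from 0.937 ± 0.211 to 14.2 ± 0.765 TPM (2.98), and ETV4 from 0.220 ± 0.0330 to 4.445 ± 0.154 TPM (2.16). The immediate-early transcription factors FOS, from 72.1 ± 3.62 to 11.15 ± 0.576 TPM (-2.59), and EGR1, from 34.1 ± 4.56 to 16 ± 1.24 TPM (-1.04), were the members that fell. These rises numbered 28, 26 and 18 when adjusted over the list alone.

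Lists of mucin, interferon-stimulated, epithelial, mitochondrial and cholesterol genes were shifted down in the knockdown. Among 11 mucin and secretory differentiation genes 0 rose, 8 fell and 3 did not pass (median -0.99 relative to all genes, camera adjusted p = 8.31e-08, adjusted p = 0.06 with an estimated correlation). The membrane mucins MUC1 from 30.2 ± 2.42 to 3.98 ± 0.166 TPM (-2.65), MUC20 from 48.2 ± 3.87 to 12.4 ± 0.343 TPM (-1.87) and MUC16 from 5.03 ± 0.734 to 1.785 ± 0.147 TPM (-1.11) were among them. Among 29 interferon-stimulated genes 5 rose, 16 fell and 8 did not pass (median -0.64 relative to all genes, camera adjusted p = 3.58e-09, adjusted p = 0.06 with an estimated correlation). IFITM1 fell from 3.08 ± 0.307 to 0.434 ± 0.156 TPM (-1.51), IFIT2 from 3.65 ± 0.430 to 0.718 ± 0.0374 TPM (-1.43) and IFITM3 from 33.2 ± 4.63 to 15.9 ± 0.30 TPM (-1.01). Among 29 genes of epithelial junctions and keratins 6 rose, 13 fell and 10 did not pass (median -0.46 relative to all genes, camera adjusted p = 1.02e-06, adjusted p = 0.158 with an estimated correlation). The tight-junction protein CLDN3 fell from 240.5 ± 43.7 to 62.8 ± 8.96 TPM (-1.91), the epithelial transcription factor ELF3 from 225 ± 11.9 to 67.6 ± 0.974 TPM (-1.72) and KRT8 from 404 ± 40.1 to 156 ± 6.94 TPM (-1.37), whereas CLDN1 rose from 20.2 ± 2.60 to 54.1 ± 3.23 TPM (1.38). With rescaled libraries 3 of these genes rose and 24 fell. Mitochondrially encoded mRNAs had 0 rises and 5 falls among 13 (median -0.54 relative to all genes, camera adjusted p = 6.77e-05, adjusted p = 0.44 with an estimated correlation), and 0 rises and 10 falls with rescaled libraries. MT-ND6 fell from 12790 ± 341 to 6794 ± 190 TPM (-0.91). Among 25 genes of cholesterol synthesis and uptake 5 rose, 6 fell and 14 did not pass (median -0.31 relative to all genes, camera adjusted p = 0.00762, adjusted p = 0.33 with an estimated correlation). With each library rescaled to its median gene 0 rose and 21 fell. Its members TM7SF2 fell from 39.0 ± 5.92 to 5.42 ± 0.753 TPM (-2.64) and INSIG1 from 5.48 ± 0.366 to 3.25 ± 0.203 TPM (-0.61), while GGPS1 rose from 8.69 ± 0.0884 to 14 ± 1.02 TPM (0.62). Adjusted over the list alone, 0 rose and 8 fell among mucins, 5 rose and 16 fell among interferon-stimulated genes, 6 rose and 13 fell among epithelial genes, 0 rose and 5 fell among mitochondrial mRNAs and 5 rose and 4 fell among cholesterol genes.

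In the test of all 15721 genes, 10308 differed between knockdown and control (8432 higher and 1876 lower, limma adjusted p below 0.05). Of the 2299 that also changed at least 2-fold, 1915 were higher and 384 lower. As deposited, the groups did not overlap in 70.8% of genes, where chance gives 10% if no shift is common to a library's genes. This share was not counted with rescaled libraries, and the median shift of 0.35 alone can separate the groups in some genes. The balance of rises and falls rests on scaling. With each library rescaled to its median gene 4620 rose and 4699 fell, 707 and 944 of them at least 2-fold. As to sign, 6496 genes passed with 1 sign under both scalings while 358 passed with opposite signs. Of 29 lists 8 passed with the preset correlation and 0 with an estimated correlation, which with rescaled libraries passed 8.

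The comparison of AGR2-overexpressing cells with their controls at 72 h asks which genes change with more AGR2. S100P rose from 13.9 ± 0.651 to 361 ± 93.0 TPM (log2 fold change 4.58, SE 0.16, adjusted p = 1.46e-08) by limma with n = 3 per group. PSCA rose from 61.2 ± 1.37 to 889.8 ± 128 TPM (log2 fold change 3.83, SE 0.12, adjusted p = 7.69e-09). KRT13 rose from 23.8 ± 0.859 to 241 ± 40.4 TPM (3.27), and the urothelial membrane protein UPK2 from 3.92 ± 0.136 to 48.3 ± 3.36 TPM (3.33). The retinoid-induced RARRES1 rose from 1.31 ± 0.0976 to 50.5 ± 1.23 TPM (4.48), ADIRF from 1.18 ± 0.0742 to 45.2 ± 8.85 TPM (4.39) and the complement protease CFD from 6.59 ± 0.342 to 109.6 ± 24.1 TPM (3.84). The prostaglandin-degrading enzyme HPGD (3.25), the small Cajal body RNA SCARNA9 (3.17), CEMP1 (3.15), the stress-induced cytokine GDF15 (3.10) and the cytochrome P450 CYP4F12 (3.08) completed the 12 largest rises.

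KRT5, a keratin of basal epithelium, fell with overexpression from 98.3 ± 3.65 to 0.80 ± 0.189 TPM (log2 fold change -5.79, SE 0.082, adjusted p = 6.23e-11) and KRT6A from 99.4 ± 1.13 to 7.15 ± 0.447 TPM (-3.62). The TGF-beta family ligands INHBA, from 37.2 ± 1.26 to 1.57 ± 0.313 TPM (-3.90), and TGFB2, from 19.2 ± 0.501 to 1.27 ± 0.285 TPM (-3.16), and the cytokines IL11, from 13.95 ± 0.863 to 0.7905 ± 0.0605 TPM (-3.06), and IL32 (-2.97) fell. CYBA fell from 32.0 ± 1.33 to 0.316 ± 0.0240 TPM (log2 fold change -4.65, SE 0.11, adjusted p = 1.25e-09) and VIM from 19.0 ± 0.349 to 1.07 ± 0.201 TPM (-3.28). The cancer-testis antigen CTAG2 (-5.14), the T-cell receptor constant segment TRBC2 (-4.75) and OSCAR (-3.40) were also among the largest falls. CTAG2 and KRT6A have close paralogs with which reads could be shared.

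Lists of secretory, interferon-stimulated and histone genes were shifted up with overexpression. Among 11 mucin and secretory differentiation genes 9 rose, 0 fell and 2 did not pass (median 1.13 relative to all genes, camera adjusted p = 3.34e-05, adjusted p = 0.0687 with an estimated correlation). MUC20 rose from 52.8 ± 0.970 to 286.5 ± 25.3 TPM (2.41), MUC1 from 50.7 ± 1.51 to 179 ± 9.08 TPM (1.80) and CEACAM6 from 55.0 ± 1.77 to 182 ± 20.3 TPM (1.70). Among 29 interferon-stimulated genes 27 rose, 1 fell and 1 did not pass (median 0.80 relative to all genes, camera adjusted p = 6.29e-09, adjusted p = 0.0687 with an estimated correlation). IFI6 rose from 12.5 ± 0.206 to 61.15 ± 13.0 TPM (2.18), IFIT1 from 2.43 ± 0.0728 to 13.5 ± 0.685 TPM (2.08) and IFITM1 from 6.77 ± 0.364 to 33.8 ± 4.11 TPM (2.16). Among 19 histone genes 13 rose, 0 fell and 6 did not pass (median 0.64 relative to all genes, camera adjusted p = 0.00641, adjusted p = 0.0687 with an estimated correlation). H2AC6 rose from 11.8 ± 0.907 to 28.9 ± 1.97 TPM (1.23) and H2BC21 from 16.4 ± 1.93 to 37.6 ± 3.84 TPM (1.15), both of which are known to give polyadenylated transcripts too. The rises numbered 10, 27 and 13 when adjusted over the list alone.

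Lists of cell-cycle, mesenchymal and other genes were shifted down with overexpression. Of 26 genes of mitosis and G2/M 25 fell and 0 rose (median -0.95 relative to all genes, camera adjusted p = 5.14e-11, adjusted p = 0.0687 with an estimated correlation). The proliferation antigen MKI67 fell from 18.3 ± 0.652 to 5.53 ± 1.97 TPM (-1.61), FOXM1 from 22.5 ± 0.913 to 8.10 ± 0.993 TPM (-1.38) and the cyclin CCNA2 from 33.8 ± 0.859 to 12.5 ± 0.678 TPM (-1.37). Of 28 genes of DNA replication and S phase 25 fell and 0 rose (median -0.54 relative to all genes, camera adjusted p = 8.2e-09, adjusted p = 0.0687 with an estimated correlation). CDC6 fell from 6.36 ± 0.227 to 2.90 ± 0.0702 TPM (-0.92), CDT1 from 15 ± 0.80 to 7.56 ± 0.590 TPM (-0.90) and FEN1 from 53 ± 0.974 to 28.4 ± 4.72 TPM (-0.89). Among 16 mesenchymal genes 1 rose, 13 fell and 2 did not pass (median -1.56 relative to all genes, camera adjusted p = 1.83e-08, adjusted p = 0.0687 with an estimated correlation). TGFBI fell from 36.8 ± 1.27 to 3.88 ± 0.150 TPM (-2.95) and the transcription factor SNAI2 from 23.1 ± 1.15 to 2.78 ± 0.356 TPM (-2.67) beside VIM. Among 26 YAP/TEAD targets 1 rose, 20 fell and 5 did not pass (median -0.66 relative to all genes, camera adjusted p = 3.6e-07, adjusted p = 0.366 with an estimated correlation). The EGFR ligand AREG fell from 4.92 ± 0.13 to 0.527 ± 0.0757 TPM (-1.96), the receptor kinase AXL from 26.2 ± 0.752 to 8.60 ± 0.670 TPM (-1.51) and CCN2 from 33.15 ± 0.332 to 12.1 ± 0.173 TPM (-1.38). Among 19 receptor tyrosine kinases and ligands 3 rose, 12 fell and 4 did not pass (median -0.80 relative to all genes, camera adjusted p = 0.00282, adjusted p = 0.417 with an estimated correlation). The EGFR ligands HBEGF, from 8.58 ± 0.264 to 1.22 ± 0.102 TPM (-2.11), and EPGN, from 3.13 ± 0.231 to 0.204 ± 0.0774 TPM (-1.78), fell. Among 25 cholesterol genes 0 rose, 18 fell and 7 did not pass (median -0.47 relative to all genes, camera adjusted p = 2.86e-06, adjusted p = 0.0687 with an estimated correlation). INSIG1 fell from 7.90 ± 0.364 to 1.49 ± 0.290 TPM (-1.85) and MSMO1 from 36.5 ± 1.22 to 12.85 ± 0.475 TPM (-1.44). The falls in these lists numbered 25, 25, 13, 20, 12 and 18 when adjusted over the list alone.

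Further lists moved down with overexpression while some of their members rose. Among 26 genes of the integrated stress response 6 rose, 16 fell and 4 did not pass (median -0.49 relative to all genes, camera adjusted p = 0.00315, adjusted p = 0.366 with an estimated correlation). The amino acid transporter subunits SLC7A5, from 198 ± 6.00 to 32.1 ± 3.48 TPM (-2.59), and SLC3A2, from 77.8 ± 1.56 to 26.0 ± 2.17 TPM (-1.55), fell, and NUPR1 rose from 2.41 ± 0.153 to 7.76 ± 1.53 TPM (1.35). Among 28 NF-kB targets and inflammatory cytokines 7 rose, 18 fell and 3 did not pass (median -0.49 relative to all genes, camera adjusted p = 0.00315, adjusted p = 0.228 with an estimated correlation). The chemokine CXCL8 fell from 12.0 ± 0.639 to 1.30 ± 0.217 TPM (-2.50) and the acute-phase protein SAA2 rose from 2.78 ± 0.194 to 11.55 ± 0.373 TPM (1.73). Among 18 TGF-beta targets 5 rose, 10 fell and 3 did not pass (median -0.48 relative to all genes, camera adjusted p = 0.00836, adjusted p = 0.416 with an estimated correlation). On protein-coding nuclear genes alone this list did not pass (camera adjusted p = 0.0574). PMEPA1 fell from 23.2 ± 0.647 to 5.29 ± 0.134 TPM (-1.94) and ID1 rose from 3.515 ± 0.221 to 26.2 ± 4.42 TPM (2.58). Among 24 hypoxia and glycolysis genes 5 rose, 14 fell and 5 did not pass (median -0.30 relative to all genes, camera adjusted p = 0.00641, adjusted p = 0.367 with an estimated correlation). The aldolase ALDOC fell from 14.6 ± 0.780 to 1.40 ± 0.121 TPM (-2.70) and the angiogenic factor VEGFA rose from 18.7 ± 0.626 to 36.25 ± 3.64 TPM (0.91). Among 26 matrix adhesion and protease genes 5 rose, 14 fell and 7 did not pass (median -0.48 relative to all genes, camera adjusted p = 0.00641, adjusted p = 0.557 with an estimated correlation). The protease inhibitor TIMP3 was among the rises, from 35.4 ± 0.787 to 119 ± 6.28 TPM (1.72). Among 15 fatty acid synthesis genes 2 rose, 6 fell and 7 did not pass (median -0.24 relative to all genes, camera adjusted p = 0.0335, adjusted p = 0.557 with an estimated correlation). It did not pass on protein-coding nuclear genes alone (camera adjusted p = 0.127) or without control replicate 1 at 24 h and overexpression replicate 1 (camera adjusted p = 0.0521). The desaturase SCD fell from 36.3 ± 1.53 to 12.8 ± 1.53 TPM (-1.44). Adjusted over the list alone, 7 rose and 16 fell in the stress response, 7 rose and 18 fell in NF-kB targets, 5 rose and 10 fell in TGF-beta targets, 5 rose and 14 fell in hypoxia genes, 5 rose and 16 fell in matrix genes and 2 rose and 7 fell in fatty acid synthesis.

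Overexpression changed 8703 of 15721 genes (4698 higher and 4005 lower, limma adjusted p below 0.05), and 1655 of them at least 2-fold (1076 higher and 579 lower). With each library rescaled to its median gene 4376 were higher and 4491 lower, and on protein-coding nuclear genes alone 3077 and 3435 (671 and 680 at least 2-fold). As deposited, the groups did not overlap in 63.1% of genes, where chance gives 10% if no shift is common to a library's genes. Of 29 lists 15 passed with the preset correlation (3 up and 12 down) and 0 with an estimated correlation, which with rescaled libraries passed 7. Replicate 1 of the overexpressing cells stood apart from the others in mitochondrial share, 37.3% against 45.8% and 47.4%.

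**Figure D3:**
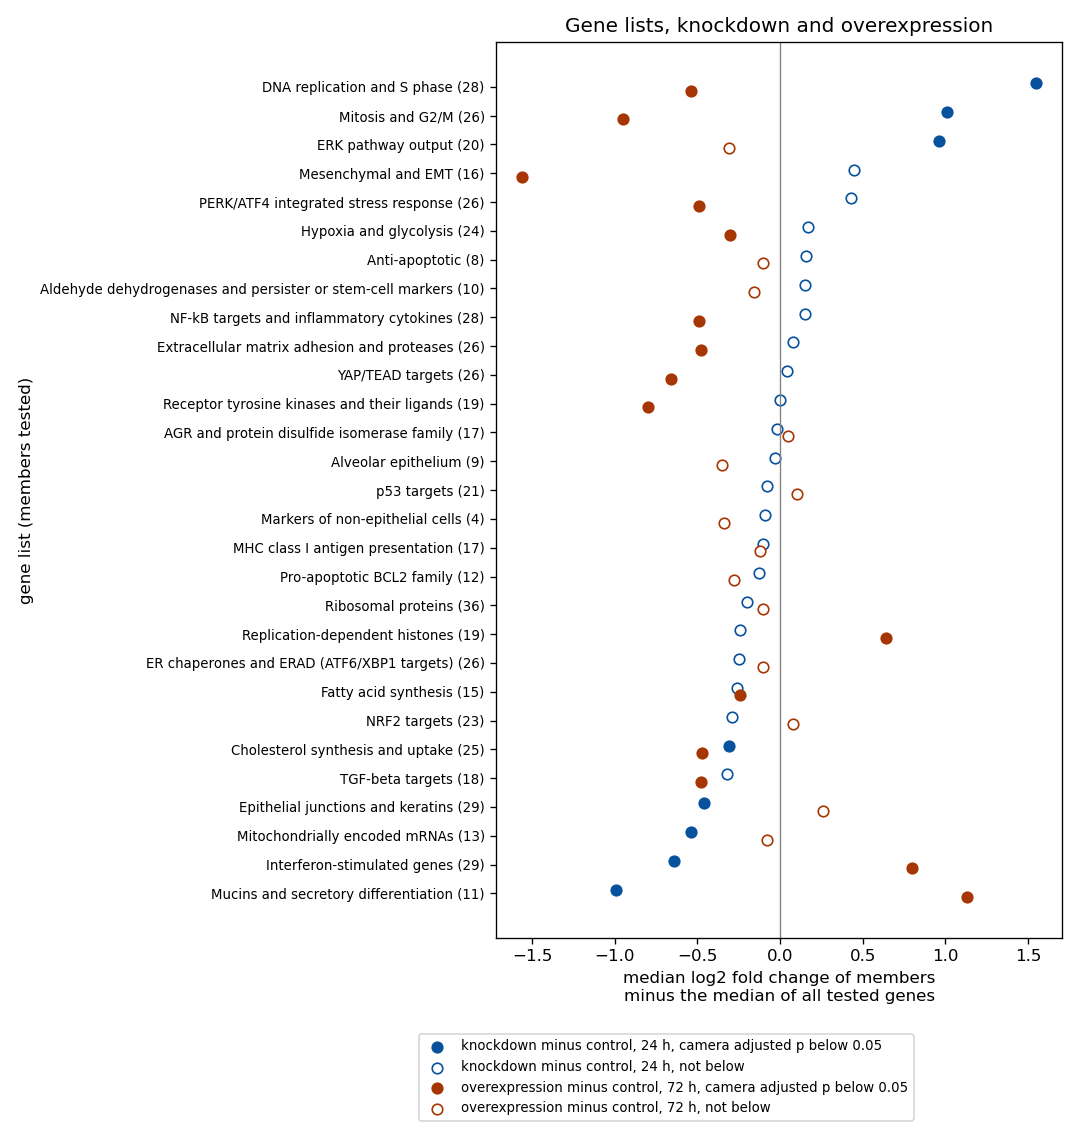
Median log2 fold change of each gene list's tested members minus the median of all tested genes (horizontal axis), for 29 lists (vertical axis, members tested in parentheses), in the knockdown at 24 h (blue) and the overexpression at 72 h (brown). Filled dots passed camera at an adjusted p below 0.05 with the preset correlation, open dots did not. DNA replication and S phase lies at 1.55 in the knockdown and -0.54 in the overexpression, mucins and secretory differentiation at -0.99 and 1.13.

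Many genes moved in opposite directions in the knockdown and in the overexpressing cells, each against the control of its time. FOS fell from 72.1 to 11.15 TPM in the knockdown and rose from 134 to 981 TPM with overexpression. PSCA, S100P and KRT13 fell in the knockdown and rose with overexpression, as did the antisense RNA GPC1-AS1 (-3.12 and 2.67). VIM, G0S2 (3.47 and -2.88) and the metallothionein MT2A (2.48 and -2.54) rose in the knockdown and fell with overexpression. Other genes moved the same way in both. CYBA fell to 0.379 ± 0.0471 TPM in the knockdown and 0.316 ± 0.0240 TPM in the overexpressing cells, against 34.3 and 32.0 TPM in their controls. The basal keratin KRT17 (-2.85 and -2.65), the ligand WNT11 (-3.0 and -2.30), GNG13 (-2.00 and -2.16), CDC42EP5 (-1.96 and -1.97), the ER-phagy receptor RETREG1 (-1.63 and -1.60) and heme oxygenase HMOX1 (-1.59 and -1.83) fell in both, and RNASE1 (3.25 and 2.14) rose in both.

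Of 6234 genes that passed in both comparisons, 3957 (63.5%) changed in opposite directions and 2277 in the same direction. 2964 rose in the knockdown and fell with overexpression, where independent lists would share 2148, and 993 did the reverse, where 561 would be shared. The same-direction genes were 1919 rises and 358 falls, with 2520 and 478 from independent lists. Fisher's exact test of sign agreement, two-sided, gave an odds ratio of 0.233 (p = 1.39e-112), and the log2 fold changes correlated across genes at Pearson r = -0.333 and Spearman rho = -0.328. Genes are not independent replicates, so this p overstates the evidence. The comparisons share no libraries. With each library rescaled to its median gene 4201 genes (70.8%) changed in opposite directions, and the same-direction genes were 722 rises and 1012 falls.

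**Figure D4:**
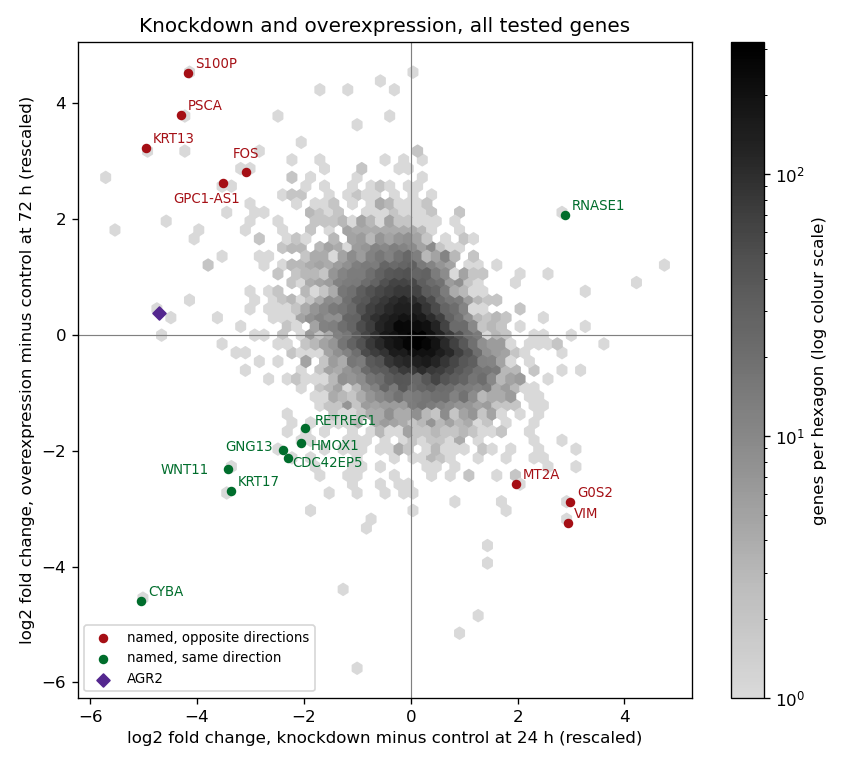
Log2 fold change in the knockdown at 24 h (horizontal axis) and with overexpression at 72 h (vertical axis) for 15721 genes, each library rescaled to its median gene. Grey hexagons are coloured by the number of genes they hold on a log scale, red dots are the 8 named genes with the largest opposite changes, green dots the 8 with the largest shared changes, and the diamond is AGR2. Among the coloured dots S100P lies highest and CYBA lowest, with rescaled overexpression changes of 4.52 and -4.59.

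The difference between the overexpression and knockdown effects was itself tested by limma. Mucin and secretory genes had higher effects with overexpression in 11 of 11 members (median 2.14 relative to all genes, camera adjusted p = 1.38e-08). Interferon-stimulated genes had higher effects in 24 and lower in 1 of 29 (median 1.64 relative to all genes, camera adjusted p = 1.89e-12). With an estimated correlation the adjusted p was 0.045 and 0.026, and on protein-coding nuclear genes alone, where neither passed, 0.206 and 0.149. Mitosis genes had lower effects with overexpression in 26 of 26 (median -1.84 relative to all genes, camera adjusted p = 9.61e-10, adjusted p = 0.103 with an estimated correlation). S-phase genes had lower effects in 28 of 28 (median -2.08 relative to all genes, camera adjusted p = 3.64e-12, adjusted p = 0.0614 with an estimated correlation), as did mesenchymal genes in 16 of 16 (median -1.23 relative to all genes, camera adjusted p = 9.85e-07, adjusted p = 0.122 with an estimated correlation). In the knockdown by itself the mesenchymal list was not shifted (10 rose, 4 fell and 2 did not pass, camera adjusted p = 0.788). Epithelial junction genes had higher effects in 17 and lower in 9 of 29 (median 0.88 relative to all genes, camera adjusted p = 0.000208, adjusted p = 0.281 with an estimated correlation), and in 19 and 2 with rescaled libraries. Adjusted over the list alone, 11 mucin and 24 interferon-stimulated genes had higher effects, and 26 mitosis, 28 S-phase and 16 mesenchymal genes lower ones. Integrated stress response genes had lower effects in 20 and higher in 5 of 26, and ERK outputs in 15 and 4 of 20. YAP/TEAD targets had lower effects in 17 and higher in 1 of 26, and hypoxia genes in 17 and 2 of 24. Histone genes had higher effects in 9 and lower in 5 of 19, and mitochondrial mRNAs in 5 and 0 of 13. For these lists the camera adjusted p ran from 0.00981 to 0.027, and from 0.106 to 0.701 with an estimated correlation. With rescaled libraries hypoxia and histone genes did not pass (camera adjusted p = 0.0744 and 0.0549), nor did hypoxia genes on protein-coding nuclear genes alone (0.115), and mitochondrial mRNAs had 9 higher effects. In the knockdown by itself, as deposited, stress response, YAP/TEAD, hypoxia and histone genes did not pass (camera adjusted p = 0.37, 0.934, 0.52 and 0.156). With overexpression by itself ERK outputs, mitochondrial mRNAs and epithelial junction genes did not pass (camera adjusted p = 0.272, 0.772 and 0.0976). For these lists a difference of effects does not mean opposite shifts in both comparisons. Across all genes 10326 of 15721 effects differed, 3164 higher and 7162 lower with overexpression, and with each library rescaled to its median gene 5059 and 4982. This difference also holds that between 24 h and 72 h of gefitinib.

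The control cells at 72 h and at 24 h of gefitinib differed as well. IGFBP5, a binding protein of insulin-like growth factors, rose from 1.55 ± 0.305 to 42.4 ± 0.951 TPM (log2 fold change 4.10, SE 0.15, adjusted p = 7.99e-08) by limma with n = 3 per group. KRT4 rose from 1.74 ± 0.0922 to 20.4 ± 1.80 TPM (2.96) and TGFB2 from 2.41 ± 0.476 to 19.2 ± 0.501 TPM (2.58). The endosomal RAB11FIP1 (2.60), the secreted FSTL1 (2.42), the phosphatase DUSP1 (2.34) and the cyclooxygenase PTGS2 (2.29) rose too. S100P fell from 56.0 ± 8.20 to 13.9 ± 0.651 TPM (-1.93) and AGR2 by the amount given above (-1.86). UPK3BL2 (-2.03), CEMP1 (-2.96), FAM25A (-1.85), the troponin TNNI2 (-1.84) and the antisense RNAs RCC2-AS1 (-3.77) and MYADM-AS2 (-2.83) fell as well.

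Mitosis genes were lower at 72 h in the controls, with 17 falls and 2 rises among 26 (median -0.62 relative to all genes, camera adjusted p = 6.87e-13, adjusted p = 0.18 with an estimated correlation). Of 28 S-phase genes 28 rose (median 0.44 relative to all genes, camera adjusted p = 6.39e-07, adjusted p = 0.18 with an estimated correlation). Of 26 genes of the integrated stress response 24 rose (median 0.54 relative to all genes, camera adjusted p = 1.42e-06, adjusted p = 0.18 with an estimated correlation). Of 26 ER chaperone genes 24 rose (median 0.39 relative to all genes, camera adjusted p = 7.22e-05, adjusted p = 0.18 with an estimated correlation). Of 28 NF-kB targets, PTGS2 among them, 28 rose (median 0.27 relative to all genes, camera adjusted p = 6.23e-05, adjusted p = 0.18 with an estimated correlation). Of 26 YAP/TEAD targets, TGFB2 among them, 25 rose (median 0.57 relative to all genes, camera adjusted p = 6.45e-06, adjusted p = 0.296 with an estimated correlation). Of 20 ERK outputs 18 rose (median 0.56 relative to all genes, camera adjusted p = 0.00016, adjusted p = 0.296 with an estimated correlation). Ribosomal protein genes had 0 rises and 9 falls among 36 (median -0.49 relative to all genes, camera adjusted p = 1.43e-10, adjusted p = 0.296 with an estimated correlation), and 0 and 34 with rescaled libraries. After removal of trends on transcript length and GC content this list did not pass camera with an estimated correlation (adjusted p = 0.453). Rises also outnumbered falls in the other 10 lists that passed as higher, such as 27 of 29 interferon-stimulated genes, 14 of 16 mesenchymal genes and 24 of 26 matrix genes (camera adjusted p from 7.22e-05 to 0.043, and adjusted p from 0.18 to 0.407 with an estimated correlation). With rescaled libraries 15 interferon-stimulated genes rose, and epithelial, cholesterol and hypoxia genes, which are among the 10, did not pass (camera adjusted p = 0.302, 0.25 and 0.503). On protein-coding nuclear genes alone these 3 lists (0.693, 0.597 and 0.867), protein disulfide isomerases (0.192) and TGF-beta targets (0.0551) did not pass. NRF2 targets passed as lower relative to all genes (median -0.30 relative to all genes, camera adjusted p = 0.00387, adjusted p = 0.277 with an estimated correlation), although 7 rose, 6 fell and 10 did not pass, and 1 rose and 16 fell with rescaled libraries. Mitochondrial mRNAs also passed as lower (median -0.36 relative to all genes, camera adjusted p = 0.000559, adjusted p = 0.296 with an estimated correlation), with 0 rises and 3 falls among 13, and 0 and 9 with rescaled libraries. Adjusted over the list alone, 17 mitosis and 4 ribosomal protein genes fell, and 28 S-phase, 24 stress-response, 24 chaperone, 28 NF-kB, 26 YAP/TEAD and 18 ERK genes rose. Across all genes 9594 of 15721 differed (8321 higher and 1273 lower at 72 h), and with each library rescaled to its median gene 4380 rose and 4132 fell. Of 29 lists 20 passed with the preset correlation and 0 with an estimated correlation, which with rescaled libraries passed 8. The constructs of the control cells are not given in the sources used here, so time and construct are not separated.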

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

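The tests of scaling for the cell-cycle genes, the 3 tests for AGR2 and the test of a common response for CYBA were chosen only after the results were seen, as were the removal of length and GC trends and the leaving out of the libraries lowest in long transcripts.

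The effects of overexpression and knockdown differed, in a test of the difference itself, for 10326 genes, of which 3164 had a higher and 7162 a lower effect with overexpression. By the same test 12 lists differed, 5 higher and 7 lower. Of 100 splits of the libraries at each time, 1, the real one, gave as many genes. The highest of the others was 6012, in a split that kept the knockdown grouping, and splits that mixed both groupings gave 0. Each of the other splits mixed at least 1 comparison, so this rank follows from the groupings of the single comparisons. It does not test whether the effects of overexpression and knockdown differ. For the lists 12 of the 100 splits gave as many, the highest other giving 16, so chance cannot be excluded for that count. For the genes that changed in opposite directions the real split gave 3957 and the highest other 0, with 1 of 100 as large. Since a gene must pass in both comparisons, and splits that mix a comparison called at most 1 gene in it, this count follows from the single comparisons and does not test the direction.

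Within a single comparison, 6 libraries allow 10 splits, too few for a share under 0.05. For genes changed by the knockdown the real split gave 10308 and the highest other 0, for overexpression 8703 and 1, and for the controls 9594 and 0, with 1 of 10 splits as large in each. For lists the knockdown gave 8 and the highest other split 8, with 4 of 10 as large. Chance can therefore not be excluded for the count of knockdown lists. The overexpression gave 15 lists against 13, and the controls 20 against 13, with 1 of 10 as large in both.

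Of 54 tested mitosis and S-phase genes 54 rose in the knockdown and 50 fell with overexpression. After rescaling of each library 54 rose and 50 fell, after removal of trends on transcript length and GC content 54 and 53, and without control replicate 1 at 24 h and overexpression replicate 1 54 and 50, which argues against scaling, these trends and these libraries as the whole cause. Each comparison has its control at the same time, so 24 h against 72 h of gefitinib cannot by itself give the rises or the falls. The knockdown and overexpression constructs and their derivation stay open, since the design ties each to its group. An influence of AGR2 itself on proliferation is a hypothesis that was not tested here.

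AGR2 RNA was 1.38-fold higher in the overexpressing cells. Rescaling left a log2 fold change of 0.38 (adjusted p = 0.0019, over 19 alternatives 9.16e-07 to 0.00462), which argues against scaling. The lowest overexpressing library, at 10.7 TPM, was above the highest control at 8.67 TPM, which argues against a control library under an overexpression label. Reads of a recoded or tagged construct may be missing from the AGR2 value, and this cannot be told apart from a small rise of 0.42, since the table holds gene totals and no reads. A loss of the transgene's expression during 72 h is a biological explanation that was not tested.

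CYBA fell to about the same level in both engineered populations. In all 2277 genes passed in the same direction in both comparisons, where independent lists would share 2998. Opposite effects lower this count whether or not the engineered cells share a response to constructs or selection, so such a response cannot be told apart. The 11 other tested genes within 200 kb of CYBA had median rescaled changes of -0.16 in the knockdown and 0.07 with overexpression (from -0.55 to 1.76 and from -0.94 to 1.01), which argues against loss of the region around it. A loss confined to CYBA, or a shared origin of the engineered cells with low CYBA, could still give this, and no biological explanation was tested.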

How the results depend on the processing

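The removal of trends, the protein-coding nuclear genes, the leaving out of libraries lowest in long transcripts and of genes overlapping the other strand were chosen only after the results were seen, as was an estimated correlation in alternatives. Under other pseudocounts, no filter, rescaling, quantile normalisation, robust shrinkage, library weights and the 6 compared libraries alone, the 5 gene counts stayed within 1.5 times their values and AGR2 kept its direction and its call, at log2 fold changes of -5.38 to -4.27 in the knockdown and 0.34 to 0.46 with overexpression over 19 alternatives. In the order knockdown, overexpression, controls, difference of effects and opposite directions, a filter of 5 TPM, which tests 8499 genes, gave 6186, 5097, 5839, 6126 and 2587. A 2-fold minimum, which by construction keeps fewer genes, gave 2299, 1655, 1248, 4635 and 318. Leaving out genes that overlap the other strand, which leaves 7314 genes and gives no value for AGR2, gave 4763, 3937, 4339, 4742 and 1829. Protein-coding nuclear genes alone (10672 tested) gave 7544, 6512, 6522, 7606 and 3250, removal of trends 9517, 9298, 8246, 10094 and 4630, and leaving out both libraries lowest in long transcripts 10350, 9037, 9603, 10321 and 4008. Leaving out each library in turn gave 9154 to 10010, 7514 to 8585, 8614 to 9174, 9480 to 10299 and 3451 to 3926. With a replicate block the counts were 9985, 8152, 9657, 9975 and 3604, and AGR2 changed by -4.30 and 0.42. After subtraction of each group's mean, same-numbered libraries of the compared groups correlated between -0.159 and 0.062 across genes. Differently numbered libraries ran from -0.138 to 0.135. These values show no strong effect shared by replicate number, and cannot tell whether the numbers pair the cultures. Of 29 lists, an estimated correlation passed 0 for the knockdown, 0 for the overexpression, 0 for the controls and 2 for the difference, and fry, which asks another question, 23, 19, 26 and 25 in the same order. An estimated correlation passed 8, 7, 8 and 5 with rescaled libraries, 6, 5, 7 and 7 after removal of trends, 0 in each on protein-coding nuclear genes and 1, 0, 0 and 2 without both libraries lowest in long transcripts. Over the other alternatives, with the preset correlation, 8 to 11, 11 to 16, 14 to 21 and 8 to 13 lists passed, the fewest under a filter of 5 TPM or without genes that overlap the other strand (overexpression 11 each, difference 10 and 8) and on protein-coding nuclear genes (controls 14). Of 5589 values of named genes under alternatives 5524 kept their direction and call, 55 lost the call and 10 changed sign. In the knockdown these were COL1A1 at -0.15 (rescaled, quantile) and 0 (trends removed), RPL6 at -0.01, RPL18 at -0.06 and RPL19 at -0.19 (rescaled), RPL19 at -0.02 and MCL1 at -0.01 (trends removed) and MT-CO2 at 0 (quantile), and with overexpression MT-ND6 at -0.03 (quantile). Apart from the smaller numbers of genes, the cause was not tested. Tools for read counts were not run, since the table holds TPM, and the 6 libraries alone give no difference of effects. Depth is unknown, so what it limits cannot be stated.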

Other observations

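The tests on protein-coding nuclear genes alone, after removal of trends and without 2 libraries (control replicate 1 at 24 h and overexpression replicate 1), and those with an estimated correlation under them or with rescaled libraries, were chosen only after the results were seen. Among 17 protein disulfide isomerase family genes 12 rose, 3 fell and 2 did not pass in the knockdown (median -0.02 relative to all genes, camera adjusted p = 0.905), and with rescaled libraries 5 rose and 8 fell. With overexpression 5 rose, 5 fell and 7 did not pass (median 0.05 relative to all genes, camera adjusted p = 0.731). AGR2, the altered gene, belongs to this list and is 1 of the 3 falls in the knockdown and 1 of the 5 rises with overexpression. TXNDC5, a member of the family, rose from 9.04 ± 0.613 to 19.8 ± 1.72 TPM (1.05) in the knockdown and fell from 20.2 ± 0.373 to 12.1 ± 0.632 TPM (-0.70) with overexpression. ER chaperone and degradation genes had 8 rises and 5 falls among 26 in the knockdown (median -0.25 relative to all genes, camera adjusted p = 0.0975, adjusted p = 0.642 with an estimated correlation), and 1 and 16 with rescaled libraries. The list passed as lower with rescaled libraries, on protein-coding nuclear genes alone and after removal of trends on transcript length and GC content (camera adjusted p = 0.000533, 0.00207 and 0.000125; adjusted p = 0.0423, 0.583 and 0.164 with an estimated correlation). Without the 2 libraries 9 rose and 5 fell (camera adjusted p = 0.0988). With overexpression 5 rose, 9 fell and 12 did not pass (median -0.10 relative to all genes, camera adjusted p = 0.506), HYOU1 falling from 95.1 ± 0.735 to 48.7 ± 5.31 TPM (-0.96). Ribosomal protein genes had 12 rises and 1 fall in the knockdown, and 0 and 21 with rescaled libraries (camera adjusted p = 0.4 and 0.000647, adjusted p = 0.981 and 0.654 with an estimated correlation). As deposited and adjusted over the list alone, 6 rose and 1 fell. Ribosomal protein genes passed as lower on protein-coding nuclear genes alone (camera adjusted p = 0.00222, adjusted p = 0.754 with an estimated correlation). They had 1 rise and 10 falls after removal of trends (camera adjusted p = 0.0886). Without the 2 libraries they had 24 and 1, with the test direction up (camera adjusted p = 0.723).

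Stem-cell and drug-tolerance markers moved apart from each other. Among 10 such genes 8 rose, 2 fell and 0 did not pass in the knockdown (median 0.15, mean -0.17 relative to all genes, camera adjusted p = 0.906), and with rescaled libraries 4 rose and 3 fell. The surface protein CD24 fell from 539.7 ± 26.7 to 82.7 ± 3.48 TPM (-2.69), while the hyaluronan receptor CD44 rose from 9.67 ± 0.980 to 58.55 ± 2.87 TPM (2.48) and the transcription factor SOX9 from 18.6 ± 1.38 to 84.7 ± 7.29 TPM (2.13). With overexpression SOX9 fell from 68.0 ± 2.46 to 36.3 ± 3.44 TPM (-0.89) and ALDH3A1 rose from 93.1 ± 2.79 to 376 ± 19.2 TPM (2.00). Among 8 anti-apoptotic genes 8 rose in the knockdown, and 2 with rescaled libraries (camera adjusted p = 0.127 as deposited and 0.392 rescaled). XIAP rose from 2.78 ± 0.259 to 7.095 ± 0.261 TPM (1.1). Among 21 p53 targets 7 rose, 9 fell and 5 did not pass with overexpression (median 0.10, test direction down, camera adjusted p = 0.736), the cell-cycle inhibitor CDKN1A falling from 8.91 ± 0.204 to 1.64 ± 0.127 TPM (-1.91) and GDF15 rising from 1.22 ± 0.101 to 18 ± 1.23 TPM (3.10). Among 23 NRF2 targets 10 rose, 7 fell and 6 did not pass with overexpression (camera adjusted p = 0.476), AKR1C1 rising from 53.5 ± 1.64 to 133 ± 12.0 TPM (1.30) and HMOX1 falling from 53.8 ± 2.26 to 14.4 ± 0.753 TPM (-1.83). Among 4 tested markers of non-epithelial cells 2 rose, 1 fell and 1 did not pass in the knockdown (median -0.09 relative to all genes, camera adjusted p = 0.906), and 1 rose and 1 fell with rescaled libraries. With overexpression 0 rose, 2 fell and 2 did not pass (median -0.34 relative to all genes, camera adjusted p = 0.206). The macrophage and lysosome protein CD68 rose from 54.8 ± 5.98 to 134 ± 15 TPM (1.27) in the knockdown and fell from 109 ± 0.567 to 66.2 ± 6.23 TPM (-0.72) with overexpression. The signs of median, mean and test differed for protein disulfide isomerases, receptor kinases, p53 targets and stem-cell markers in the knockdown, and for protein disulfide isomerases, alveolar genes and p53 targets with overexpression, none of which passed. Adjusted over the list alone, 8 rose and 2 fell among stem-cell markers and 8 anti-apoptotic genes rose in the knockdown, and 7 rose and 9 fell among p53 targets and 10 rose and 7 fell among NRF2 targets with overexpression.

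The antisense RNAs named for the controls varied between libraries of a group. RCC2-AS1 stood at 42.4, 12.6 and 3.31 TPM in the 24 h controls, and MYADM-AS2 at 12.6, 6.38 and 2.59 TPM. In the overexpressing cells RCC2-AS1 reached 3 TPM in replicate 1 and at most 3.02e-05 TPM in the others.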
